A study of Mus musculus with 5 samples.

How the data were processed

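RNA from NK cells of mouse spleen was measured in 5 libraries, 3 labelled Fli1 KO and 2 labelled NTC, and groups were taken from the labels. Per the labels' protocols, total RNA was extracted with a column kit, and libraries were prepared from 10 ng with a kit that enriches transcripts by probe capture. Per the submitters' processing notes, reads were checked with FastQC 0.12.0, trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.11 to mm10. The counter, its strand setting, the annotation release and the handling of reads with several positions are not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene ID, not normalized, with 0 columns beyond the 5 libraries and no line for unassigned reads. The libraries are numbered replicates, but the labels do not say that they come from separate animals, so the p-values measure only the spread between these samples.

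IDs were matched to symbols in the gene name table supplied with the reference. Of 56691 IDs, 52073 (91.9%) had one. The other 4618 kept their ID. Coordinates, gene types, exon lengths and GC content came from GENCODE release M21 on GRCm38, the assembly also called mm10. The same 52073 IDs were found there. The release behind the deposited table is not given. The symbol Aldoa belongs to 2 IDs, which were both tested.

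Totals ran from 4718390 to 5643791 counts per library. Genes were kept with edgeR's filterByExpr at its default minimum of 10 counts, which left 30580 of the 52871 genes with any count. Counts were scaled with TMM factors. Fli1 KO was compared with NTC with edgeR's robust quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), adjusted with Benjamini-Hochberg. A gene is called where its adjusted p is under 0.05, with no threshold on fold change. The SE of a log2 fold change was taken from the fitted coefficient and its F statistic. Means and SDs are of CPM. The common biological coefficient of variation was 0.120. Binomial intervals are Wilson intervals at 95%, and intervals cover counting error only.

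For 32 gene lists the members were fixed before the data were examined, as were the tests, the settings to be varied and the rule for naming genes. The lists cover protein homeostasis (chaperones, ER stress, proteasome, autophagy), nutrient use (integrated stress response, transporters, glycolysis and hypoxia, oxidative phosphorylation, lipid synthesis), growth and p53, signalling (immediate early, cytokine, interferon, TGF-beta and migration genes), NK states and receptors, ETS factors, and markers of other cells. Each was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 32 lists. This called 15 lists. With an estimated correlation 0 were called, and 1 list had an unadjusted p under 0.05. fry, which tests whether a list's genes move on balance one way, called 0. fry's mixed test asks whether they change in either direction. Neither compares a list with other genes.

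The text names Fli1 and the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with a mean of at least 5 CPM and groups that do not overlap, passing over genes without a proper symbol and receptor segments. It also names, per list, up to 4 called members with the smallest adjusted p (or the 1 member with the smallest p where none was called) and any member that is one of 5 or fewer called. This gave 62 genes, 1 of which is not reported here. Further list members are named as examples without a call.

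The settings varied were DESeq2's size factors, upper-quartile factors, library size alone, no filter, a filter of 5 CPM in 2 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0 and limma-voom. Where a left-out library leaves 1 NTC library, its spread is assumed to be that of the Fli1 KO libraries. The difference between NTC 1 and NTC 2 then drops out of the spread. Counts of calls and adjusted p from such fits are therefore no measure of how strong a change is. Added after seeing the data were a fit on genes over 3 times background and per-library lowess corrections (span 0.3) for GC content and for exon length. Background was the count per kb of exon on 1455 autosomal olfactory and vomeronasal receptor genes (5432.638 kb), which NK cells do not use. It was scaled to each gene's exon length. This takes the density per kb on receptor genes to hold for all genes, which was not tested in these probe-capture libraries. With 3 against 2 libraries no other splits of the samples were counted.

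The fit was tested on simulated data drawn from the means, library sizes and spread of these 30580 genes with 200 genes changed. Among genes over 3 times background it recovered 20% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold, and among the others 0%, 38% and 92%. Of 125 calls 9 were false. Camera called a planted list of 30 genes shifted by 0.5 on the log2 scale. Of 200 random lists 2 had a p under 0.05. The simulated genes were independent, so this does not measure how correlation between real genes affects the list test. The random lists held only genes over 3 times background, which had no common shift in the simulation. In the real data these genes had a median log2 fold change of 0.11, and all tested genes −0.02. The share of random lists with a small p therefore does not carry over to the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes without a symbol were tested but are not named.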

Results

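RNA was profiled in natural killer (NK) cells from mouse spleen after CRISPR editing with a guide against Fli1 (3 libraries labelled Fli1 KO) or with the control labelled NTC (2 libraries). Fli1 encodes a transcription factor of the ETS family, and the series title places it in protein homeostasis under nutrient stress and in the persistence of NK cells in solid tumours. The libraries were made from total RNA by probe capture. They held 5487027, 5643791 and 5164623 counts for Fli1 KO 1 to 3, and 5445718 and 4718390 for NTC 1 and NTC 2. Of 56691 listed genes, 30580 had enough counts to be tested, and 7678 of these lay over 3 times the background, the density of counts on genes that NK cells do not use.

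Fli1 RNA itself (ENSMUSG00000016087, GRCm38 chromosome 9, 32422204 to 32542861) was present in every library, at 390, 320 and 361 CPM (counts-per-million, scaled with TMM factors) in the libraries labelled Fli1 KO and at 322 and 279 CPM in those labelled NTC. The group means were 357 ± 34.9 CPM (SD, n = 3) and 301 ± 30.6 CPM (SD, n = 2), a log2 fold change of 0.25 (SE 0.14). The groups overlapped (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.641). A count over the whole gene does not check the labels, because small insertions and deletions at a cut site leave most of a transcript countable and the guide's position is not given in the sources used here. All directions given for Fli1 KO libraries therefore rest on the labels.

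Immediate early genes, whose transcripts appear within minutes of a signal at the cell surface, led the genes that rose. Egr1, a zinc-finger transcription factor induced by MAP kinase signalling (ENSMUSG00000038418, GRCm38 chromosome 18, 34859823 to 34864984), rose 16.7-fold, from 47.5 ± 6.62 CPM (SD, n = 2) in NTC to 794 ± 187 CPM (SD, n = 3) in Fli1 KO (log2 fold change 4.06, SE 0.21, edgeR adjusted p = 3.0e-10). Ier2 rose 5.06-fold (59.0 ± 4.03 to 299 ± 71.5 CPM), Ier3, a survival factor, 4.56-fold (12.5 ± 2.91 to 57.6 ± 11.5 CPM), and Junb, a subunit of the AP-1 transcription factor, 4.11-fold (193 ± 27.3 to 794 ± 236 CPM). Fos, its dimer partner, rose 4.56-fold from a low level (2.88 to 13.1 CPM, a mean of 2.48 times background). Its NTC value lay below the background of 3.69 CPM expected from the gene's length, so the size of this fold is uncertain. Irs2, the adaptor that links insulin and cytokine receptors to PI3 kinase, rose 5.52-fold (55.9 ± 15.8 to 308 ± 58.2 CPM). Klf2, a transcription factor of quiescent lymphocytes, rose 4.46-fold (11.4 ± 3.06 to 51.2 ± 0.886 CPM), Csrnp1, a nuclear transcriptional activator, 4.44-fold (20.9 to 92.6 CPM), the early activation marker Cd69 3.96-fold (39.8 ± 2.54 to 158 ± 20.9 CPM) and the small GTPase gene Rhob 3.92-fold (30.4 ± 5.78 to 120 ± 13.1 CPM). Each of these 10 genes kept its call and its direction when any 1 library was left out.

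Among called genes with a mean of at least 5 CPM and a proper symbol, those that fell most were Hic1, which encodes a transcriptional repressor (ENSMUSG00000043099, GRCm38 chromosome 11, 75164565 to 75169519), and Arl4d, which encodes a small GTPase of the cell periphery. Hic1 was 3.37-fold lower (73.0 ± 15.9 CPM in NTC, n = 2, and 21.6 ± 4.86 CPM in Fli1 KO, n = 3; log2 fold change −1.75, SE 0.17, edgeR adjusted p = 4.5e-06) and Arl4d 3.31-fold lower (47.9 ± 4.95 and 14.4 ± 1.30 CPM, adjusted p = 1.2e-06). Cd160, a receptor of NK cells for MHC class I and HVEM, went from 47.7 ± 9.35 to 20.5 ± 2.74 CPM (log2 fold change −1.22, SE 0.16). The sugar transporter gene Slc2a6 (−1.11, 20.3 to 9.42 CPM, 2.77 times background), the cytokine gene Tnfsf14 (−1.02), the lysosomal sulfatase gene Sgsh (−0.98), the adhesion receptor gene Adgrg5 (−0.92), the NF-kappaB modulator gene Nfkbid (−0.91) and the lymphocyte transcription factor gene Irf4 (−0.90) also fell. So did H2-K2 (−0.91), an MHC class I pseudogene. How reads shared with its paralogues were counted is not given, which leaves its value uncertain. Hic1, Arl4d and Cd160 kept their calls when any 1 library was left out. The other 7 did not. Without Fli1 KO 1 their log2 fold changes were −1.09 to −0.77 with adjusted p from 0.0679 to 0.192, and without NTC 2 that of Adgrg5 was −0.56 (adjusted p = 0.322). Without Fli1 KO 3, Sgsh, Irf4, Adgrg5 and H2-K2 were at −0.97 to −0.88 (adjusted p from 0.0502 to 0.197), without Fli1 KO 2 Adgrg5 and H2-K2 at −0.81 and −0.86 (0.0710 and 0.0608), and without NTC 1 H2-K2 at −0.71 (0.0898).

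**Figure D1:**
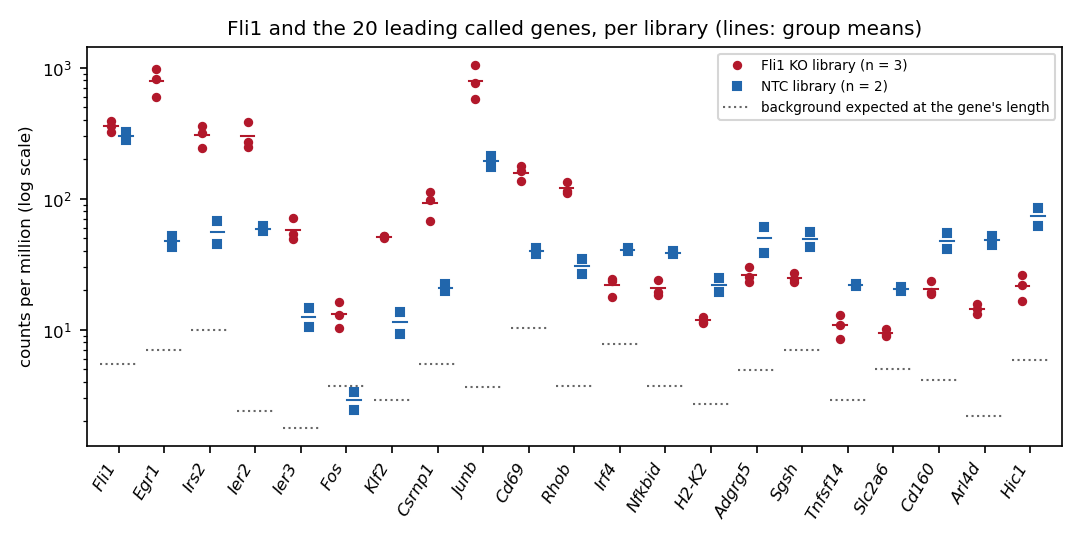
CPM on a log axis for Fli1, the 10 called genes that rose most and the 10 that fell most among those with a mean of at least 5 CPM and a proper symbol, with one point per library (circles, Fli1 KO, n = 3; squares, NTC, n = 2), short lines at the group means and dotted lines at the background expected from the gene's length. Egr1 stood at 794 CPM in Fli1 KO and 47.5 CPM in NTC, and Fli1 at 357 and 301 CPM.

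In all, 140 genes were called higher and 27 lower in Fli1 KO, and 60 of the higher and 7 of the lower ones differed by at least 2-fold. At an unadjusted p under 0.05 there were 2735 genes. The calls comprised 116 higher and 22 lower protein-coding genes, and 153 of the 167 lay over 3 times background. In all 167 the 3 Fli1 KO libraries lay on one side of both NTC libraries, as they did in 25.6% of all tested genes, where chance gives 20%. Groups separated in this way make a change of sign unlikely when 1 library is left out. Scaling by library size alone moved the median of all genes by −0.13 and gave 92 higher and 71 lower genes. Of these, 117 were among the 167. A fit on genes over 3 times background, whose median was 0.11 with all genes fitted, gave 139 higher and 59 lower. The balance of higher to lower calls therefore depends on the scaling and on the genes fitted. Calls numbered 46 higher and 3 lower without Fli1 KO 1, 219 and 22 without Fli1 KO 2, 57 and 7 without Fli1 KO 3, 703 and 174 without NTC 1, and 111 and 26 without NTC 2, and every one of the 167 kept its sign in each.

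Protein homeostasis was examined first in genes of the endoplasmic reticulum (ER), where secreted and membrane proteins fold. Hspa5, the main ER chaperone, rose 1.64-fold (209 ± 25.2 CPM in NTC, n = 2, to 342 ± 67.7 CPM in Fli1 KO, n = 3; log2 fold change 0.71, SE 0.16, edgeR adjusted p = 0.0434). Xbp1, a transcription factor of the unfolded protein response, rose 2.22-fold (54.9 ± 12.3 to 122 ± 11.1 CPM, log2 fold change 1.15), and Eif2ak3, the stress kinase PERK, 1.66-fold (93.2 ± 2.36 to 155 ± 9.26 CPM, 0.73). Ppp1r15a, the phosphatase subunit that restores translation after stress and also an early response gene, rose 3.32-fold (18.3 ± 4.84 to 61.2 ± 10.7 CPM, 1.73). Ddit3, the death-linked factor CHOP, had a log2 fold change of −0.59 that was not called (adjusted p = 0.319). Of 41 tested ER stress genes, 4 were called higher and 0 lower, and 10 and 1 with p adjusted over the list alone. The median log2 fold change was 0.35, above other genes by limma's camera test (adjusted p = 8.0e-09), although adjusted p = 0.738 with an estimated correlation between genes. Without NTC 1, 12 of these genes were called higher. Without NTC 2 the median was 0.19 (camera adjusted p = 9.5e-04) and Hspa5 lost its call (0.60, adjusted p = 0.224), as it did without Fli1 KO 1 (0.60, 0.482) or Fli1 KO 3 (0.69, 0.426). Hspa5 was also not called with median-of-ratios size factors (0.73, 0.0570), library size alone (0.58, 0.0904) or limma-voom (0.70, 0.0590). Eif2ak3 was not called without Fli1 KO 1 (0.70, 0.111) or Fli1 KO 3 (0.75, 0.158).

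Among the remaining protein homeostasis genes, Hsp90aa1, the inducible cytosolic HSP90, had the smallest p of 41 chaperones (61.1 ± 16.6 CPM in NTC, n = 2, and 96.3 ± 16.4 CPM in Fli1 KO, n = 3; log2 fold change 0.65, edgeR adjusted p = 0.114), and Lamp1, a lysosomal membrane protein gene, that of 48 autophagy and lysosome genes (−0.42, adjusted p = 0.281). The autophagy receptor gene Sqstm1 stood at 284 ± 20.9 CPM in NTC and 334 ± 28.9 CPM in Fli1 KO (adjusted p = 0.651). Of 56 proteasome and ubiquitin genes 1 was called higher and 0 lower. edgeR called 0 chaperones (5 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom) and 0 autophagy genes (7 unadjusted, 0 by DESeq2, 1 by limma-voom). With p adjusted over the list alone, 4 chaperones, 3 proteasome genes and 0 autophagy genes were higher and 0 lower. The medians were 0.13 for chaperones (camera adjusted p = 1.9e-04), 0.13 for the proteasome (1.8e-04) and 0.11 for autophagy (0.0126), each with adjusted p = 0.738 with an estimated correlation. The median of all 7678 genes over 3 times background was 0.11, and in a fit restricted to these the medians were −0.01, 0.01 and 0.01 (adjusted p = 0.484, 0.484 and 0.931). With library size alone as the scaling they were −0.0038 for the proteasome and −0.0162 for autophagy, where all genes had a median of −0.14. Without NTC 1 the medians were 0.30, 0.26 and 0.14, and without Fli1 KO 2 they were 0.28, 0.25 and 0.18. No call on these lists remained without NTC 2 (0.03, 0.08 and 0.08, adjusted p = 0.389, 0.215 and 0.163). Those on the proteasome and autophagy also ended without Fli1 KO 1 (0.06 and 0.05, adjusted p = 0.105 and 0.20), and that on autophagy with library size alone (0.0825) and with the stricter filter (0.09, 0.0800). Without NTC 1, 4 chaperones, 5 proteasome genes and 2 autophagy genes were called higher.

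Among genes linked to nutrient stress, the RNA of Atf4 was examined first. Atf4 encodes a transcription factor that adapts cells to amino acid shortage. The labels give no culture conditions for these libraries, so whether any met such a shortage is unknown. Atf4 rose 1.70-fold (106 ± 19.2 CPM in NTC, n = 2, to 180 ± 21.3 CPM in Fli1 KO, n = 3; log2 fold change 0.76, SE 0.15, edgeR adjusted p = 0.0143), Cebpb, its partner, 2.18-fold (14.6 ± 2.06 to 31.9 ± 6.93 CPM, 1.13) and Eif4ebp1, a translational repressor and target of ATF4 and mTOR, 2.48-fold (11.9 ± 2.05 to 29.9 ± 5.73 CPM, 1.31). Asns, the asparagine synthetase gene downstream of ATF4, stood at 6.15 ± 1.60 and 11.1 ± 1.75 CPM (adjusted p = 0.192). Of 35 tested genes of the integrated stress response and amino acid synthesis, these 3 were called higher and 0 lower, and 5 and 0 with p adjusted over the list alone. Their median of 0.23 exceeded that of other genes in camera (adjusted p = 2.6e-05, with adjusted p = 0.738 with an estimated correlation). Without NTC 1 the median was 0.44 with 12 genes called higher, and without Fli1 KO 2 it was 0.35. Without NTC 2 it was 0.11 (0.132) and Atf4 0.60 (0.175). Atf4 was also not called without Fli1 KO 1 (0.70, 0.229) or Fli1 KO 3 (0.76, 0.219), and Cebpb not without Fli1 KO 1 (0.96, 0.10).

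Nutrient transporter genes lay in both directions, 14 positive and 14 negative. Of 28 tested, Slc2a6 was called lower (−1.11, and −1.09 with adjusted p = 0.0679 without Fli1 KO 1) and 0 were called higher, and 2 were higher and 1 lower with p adjusted over the list alone. Slc2a1, the main glucose transporter gene, stood at 71.8 ± 52.5 CPM in NTC and 178 ± 27.9 CPM in Fli1 KO (log2 fold change 1.30, SE 0.57, edgeR adjusted p = 0.636), and Slc3a2, the heavy chain of amino acid transporters, at 63.6 ± 2.49 and 90.4 ± 16.2 CPM (0.50, adjusted p = 0.212). The median was 0.00 (camera adjusted p = 0.634). It was 0.18 without NTC 1 (adjusted p = 0.0137, with 7 genes called higher and 1 lower) and −0.13 without NTC 2 (adjusted p = 0.411).

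Genes of glycolysis and hypoxia, tested as 1 list, lay higher in Fli1 KO almost throughout, with 35 of 36 positive. Mxi1, a MAX-binding antagonist of MYC induced in hypoxia, was the only one called by edgeR, against 2 by DESeq2 and 8 by limma-voom (34.4 ± 5.80 CPM in NTC, n = 2, to 69.2 ± 9.23 CPM in Fli1 KO, n = 3; log2 fold change 1.001, SE 0.16, edgeR adjusted p = 1.8e-03), with 8 higher and 0 lower when p was adjusted over the list alone. Aldoa, Pgk1 and Pfkp, which encode enzymes of glycolysis, had log2 fold changes of 0.83, 0.77 and 1.04 (adjusted p = 0.240, 0.319 and 0.174). Pfkp spread more widely between the NTC libraries (282 ± 134 CPM) than between the Fli1 KO libraries (580 ± 48.5 CPM). The median of the list was 0.63 (camera adjusted p = 3.6e-16, with adjusted p = 0.738 with an estimated correlation), 0.26 without NTC 2 (6.5e-05) and 1.20 without NTC 1, where 27 genes were called higher. Without Fli1 KO 1, Mxi1 was not called (0.94, adjusted p = 0.0652).

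Mitochondrial and lipid genes had medians that moved with the library left out. Cox7c, a subunit of cytochrome oxidase, had the smallest p of 88 genes of oxidative phosphorylation (21.2 ± 1.90 CPM in NTC, n = 2, and 33.8 ± 2.86 CPM in Fli1 KO, n = 3; log2 fold change 0.67, edgeR adjusted p = 0.0636). Me1, the malic enzyme gene, had that of 33 genes of cholesterol and fatty acid synthesis, near background (8.41 and 5.50 CPM, −0.62, adjusted p = 0.406). edgeR called 0 genes of either list (13 and 1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and 1 higher and 0 lower in the first and 0 in the second with p adjusted over the list alone. The medians were 0.20 (camera adjusted p = 8.4e-07) and 0.17 (0.00763), with adjusted p = 0.738 with an estimated correlation for both. Without NTC 1 the medians were 0.38 with 8 genes called higher (7.5e-10) and 0.78 with 11 called higher (1.2e-09), and without Fli1 KO 2 they were 0.31 and 0.41. Both calls ended without NTC 2 (0.05, adjusted p = 0.190, and −0.12, adjusted p = 0.215), and that on lipid genes also without Fli1 KO 1 (0.08, 0.367) or Fli1 KO 3 (0.12, 0.125) and among genes over 3 times background (0.14, 0.217).

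**Figure D2:**
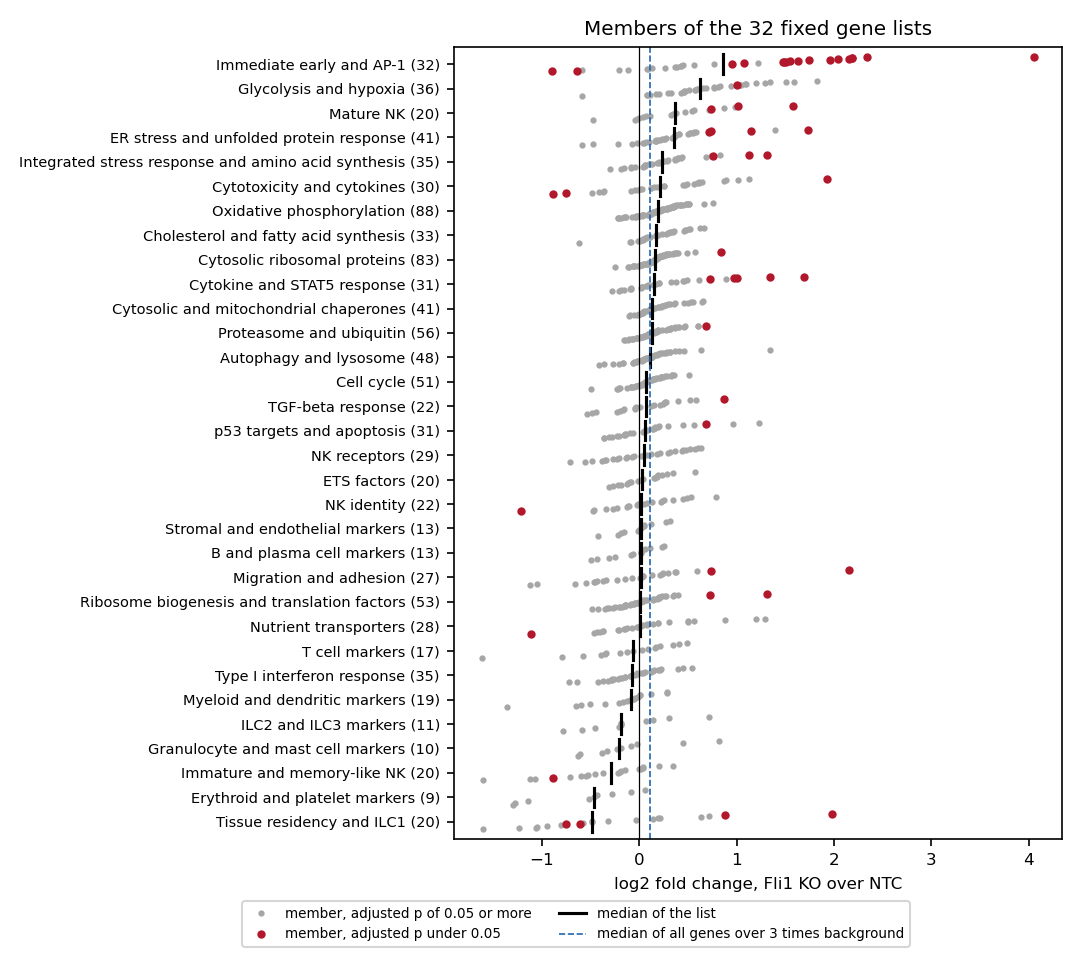
Log2 fold changes (Fli1 KO over NTC) of the members of the 32 fixed gene lists, with one point per tested gene, red where the adjusted p was under 0.05, black bars at each list's median and the number tested in brackets. The medians ran from 0.86 for immediate early and AP-1 genes to −0.48 for tissue residency genes (−0.09 without NTC 2), and the dashed line marks the median of 0.11 of all genes over 3 times background.

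NK cell maturation was read from genes of late and early stages. Among the late genes Itgam, the integrin chain CD11b, rose 1.67-fold (50.9 ± 16.5 CPM in NTC, n = 2, to 85.6 ± 5.46 CPM in Fli1 KO, n = 3; log2 fold change 0.74, SE 0.16, edgeR adjusted p = 0.0368). Irf8, a transcription factor of NK maturation and antiviral responses, rose 2.03-fold (333 ± 61.0 to 675 ± 129 CPM, 1.02) and Serpinb9b, a granzyme inhibitor gene, 2.98-fold (34.4 ± 4.86 to 103 ± 25.3 CPM, 1.58). Among the early genes Xcl1, a chemokine gene that attracts dendritic cells, was 1.85-fold lower (252 ± 43.5 and 136 ± 15.7 CPM, −0.89, adjusted p = 0.00241), and Tcf7, the transcription factor TCF-1 of immature lymphocytes, stood at 264 ± 101 and 125 ± 29.0 CPM (−1.07, adjusted p = 0.211). Of 20 mature genes 3 were called higher and 0 lower, and 10 and 1 with p adjusted over the list alone (median 0.37, camera adjusted p = 2.5e-06). Of 20 immature genes 0 were called higher and 1 lower, and 0 and 8 with p adjusted over the list alone (median −0.29, camera adjusted p = 0.00170). DESeq2 and limma-voom each called 3 immature genes. Among genes over 3 times background the immature median was −0.66 (3.1e-05). Without NTC 1, 9 immature genes were called lower, and 10 mature genes higher and 1 lower. Both lists had adjusted p = 0.738 with an estimated correlation, and the mature median was 0.63 without NTC 1. Both calls ended without NTC 2 (0.19, adjusted p = 0.0685, and −0.07, adjusted p = 0.269). Itgam was 0.46 without NTC 2 (0.468), 1.14 without NTC 1 and not called without Fli1 KO 1 (0.71, 0.372) or Fli1 KO 3 (0.75, 0.284). Without Fli1 KO 1 or Fli1 KO 3 neither Irf8 (0.90 and 1.02, adjusted p = 0.102 and 0.0862) nor Xcl1 (−0.79 and −0.90, adjusted p = 0.102 and 0.0802) was called.

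Effector genes included both directions. Ifng, the interferon gamma gene, rose 3.81-fold (12.9 ± 1.93 CPM in NTC, n = 2, to 49.4 ± 8.10 CPM in Fli1 KO, n = 3; log2 fold change 1.93, SE 0.18, edgeR adjusted p = 1.7e-06). Tnfsf10, the death ligand TRAIL, was 1.69-fold lower (69.8 ± 3.15 and 41.4 ± 1.73 CPM, −0.76). The pore-forming Prf1 stood at 737 ± 264 and 1345 ± 306 CPM (0.87, adjusted p = 0.192) and the protease gene Gzmb at 1545 ± 685 and 2361 ± 676 CPM (0.61, adjusted p = 0.692). Of 30 cytotoxicity and cytokine genes 1 was called higher (Ifng) and 2 lower (Xcl1 and Tnfsf10), and 9 and 3 with p adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.00763, with adjusted p = 0.738 with an estimated correlation), and 0.38 without Fli1 KO 2. Without NTC 1, 10 genes were called higher and 2 lower. The call ended without NTC 2 (0.22, 0.136), without Fli1 KO 1 (0.12, 0.0926), with the stricter filter (0.16, 0.0577) and among genes over 3 times background (0.22, 0.184). Tnfsf10 was not called without Fli1 KO 1 (−0.76, 0.0905) or Fli1 KO 3 (−0.76, 0.13).

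Residency genes were called in both directions. Cd69 and Rgs1, a brake on chemokine receptor signalling (66.0 ± 6.80 CPM in NTC, n = 2, to 122 ± 23.2 CPM in Fli1 KO, n = 3; log2 fold change 0.88, SE 0.16, edgeR adjusted p = 0.00695), were called higher, and Tnfsf10 and the lipid phosphatase gene Inpp4b (125 ± 7.46 to 82.0 ± 2.04 CPM, −0.61, adjusted p = 0.0261) lower, among 20 genes of tissue residency and type 1 innate lymphoid cells. With p adjusted over the list alone, 4 were higher and 5 lower. The median was −0.48 (camera adjusted p = 0.167). It was −0.53 without NTC 1 (0.00250), −0.09 without NTC 2 (0.859) and −0.06 among genes over 3 times background (0.819). fry's mixed test, which asks whether members changed in either direction, gave adjusted p = 0.0207. Rgs1 and Inpp4b were not called without Fli1 KO 1 (0.81 and −0.62, adjusted p = 0.17 and 0.214) or Fli1 KO 3 (0.81 and −0.58, adjusted p = 0.17 and 0.418). Inpp4b was also not called without Fli1 KO 2 (−0.58, 0.0710) or NTC 2 (−0.54, 0.196). Of 22 NK identity genes 0 were called higher and 1 lower (Cd160), and 4 and 3 with p adjusted over the list alone (median 0.02, camera adjusted p = 0.634). Of 29 NK receptor genes edgeR called 0 (14 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and 7 higher and 1 lower with p adjusted over the list alone (median 0.05, camera adjusted p = 0.264). Without NTC 1, 5 identity genes were called higher and 3 lower, 4 receptor genes higher and 2 lower, and 2 residency genes higher and 8 lower. Without NTC 2, 2 receptor genes were called higher, and the GC correction called 3 receptor genes lower. Ctla4, an inhibitory receptor, had the smallest p (23.1 ± 4.51 and 35.8 ± 5.44 CPM, 0.63, adjusted p = 0.144).

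Immediate early and AP-1 genes formed the list with the largest median, except without NTC 1, where the glycolysis and hypoxia genes exceeded them (1.20 against 0.92). Beside Egr1, Ier2 and Klf2, Egr2, a relative of Egr1 that restrains lymphocyte activation, rose 3.09-fold (31.9 ± 0.977 CPM in NTC, n = 2, to 98.5 ± 6.43 CPM in Fli1 KO, n = 3; log2 fold change 1.63, SE 0.14, edgeR adjusted p = 7.3e-07). Jun, the founding AP-1 subunit, stood at 134 ± 14.6 and 161 ± 7.24 CPM (0.26, adjusted p = 0.589). Of 32 genes 15 were called higher and 2 lower, and 22 and 2 with p adjusted over the list alone. The lower ones included Irf4. There were 0 lower calls without Fli1 KO 1 or Fli1 KO 3, and 1 (Irf4) without Fli1 KO 2, without NTC 2 and with median-of-ratios size factors. The median was 0.86 (camera adjusted p = 1.2e-19), and it stayed at 0.82 to 0.97 with the call kept and with 15 or 16 members called higher when any 1 library was left out. An estimated correlation gave p = 0.0348 and adjusted p = 0.738. fry's mixed test gave adjusted p = 0.0268. Irf4 was not called without Fli1 KO 1 (−0.77, adjusted p = 0.117) or Fli1 KO 3 (−0.97, adjusted p = 0.0502).

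Calls among genes of cytokine signalling were all upward. Cish, a feedback inhibitor of interleukin-15 signalling in NK cells, rose 2.54-fold (40.3 ± 6.49 CPM in NTC, n = 2, to 103 ± 14.4 CPM in Fli1 KO, n = 3; log2 fold change 1.34, SE 0.16, edgeR adjusted p = 3.5e-05). Socs1 and Socs3, inhibitors of the same family, rose 2.01-fold and 1.97-fold, Osm, the oncostatin M gene, 3.24-fold (16.6 ± 1.97 to 54.3 ± 16.9 CPM), and Myc, a growth regulator, 1.65-fold (115 ± 16.8 to 191 ± 27.0 CPM, adjusted p = 0.0225). Of 31 cytokine and STAT5 genes these 5 were called higher and 0 lower, and 8 and 0 with p adjusted over the list alone. The median was 0.15 (camera adjusted p = 2.6e-05, with adjusted p = 0.738 with an estimated correlation). The median was 0.26 without NTC 1, where 13 genes were called higher, 0.25 without Fli1 KO 2 and 0.07 among genes over 3 times background, with the call kept. Myc was not called without Fli1 KO 1 (0.70, 0.260), Fli1 KO 3 (0.66, 0.370) or NTC 2 (0.59, 0.191), and Socs3 not without Fli1 KO 1 (0.79, 0.192) or Fli1 KO 3 (1.01, 0.0965).

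For growth, Rps4x, a protein of the small ribosomal subunit, was the only ribosomal protein gene of 83 called (51.8 ± 1.77 CPM in NTC, n = 2, to 92.8 ± 25.6 CPM in Fli1 KO, n = 3; log2 fold change 0.84, SE 0.18, edgeR adjusted p = 0.0341), also with p adjusted over the list alone (1 higher and 0 lower). Its call ended without Fli1 KO 1 (0.60, adjusted p = 0.245), Fli1 KO 3 (0.98, 0.0548) or NTC 2 (0.81, 0.0515). It also ended with limma-voom (0.80, 0.0592), with the stricter filter (0.81, 0.0516) and among genes over 3 times background (0.71, 0.0777), and how reads shared with processed pseudogenes were counted is not given. The median of these genes was 0.16 (camera adjusted p = 2.6e-05, with adjusted p = 0.738 with an estimated correlation), and it was 0.32 without NTC 1, where 4 genes were called higher, and 0.29 without Fli1 KO 2. The call ended without NTC 2 (0.03, 0.695), without Fli1 KO 1 (0.04, 0.226) and among genes over 3 times background (0.04, 0.346). Of 53 genes of ribosome biogenesis and translation 2 were called higher (Myc, 0.59 with adjusted p = 0.191 without NTC 2, and Eif4ebp1) and 0 lower, and 2 and 0 with p adjusted over the list alone. Their median was 0.01 (camera adjusted p = 0.507). It was 0.16 without NTC 1 (0.00773, with 5 genes called higher) and 0.09 without Fli1 KO 2 (0.00998), but −0.08 without NTC 2 (0.389), −0.02 without Fli1 KO 1 (0.864) or Fli1 KO 3 (0.872) and −0.10 among genes over 3 times background (0.267).

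For cell division, the NTC libraries stood further apart than the groups did. Mki67, a marker of dividing cells, stood at 874 ± 402 CPM in NTC (n = 2) and 760 ± 173 CPM in Fli1 KO (n = 3; edgeR adjusted p = 0.914), and Plk1, a mitotic kinase gene, had the smallest p (−0.50, adjusted p = 0.692). edgeR called 0 of 51 cell cycle genes (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and 0 with p adjusted over the list alone, but 19 higher without NTC 1 and 1 lower without NTC 2. The median was 0.07 (camera adjusted p = 0.0534), 0.59 without NTC 1 (7.6e-13), −0.29 without NTC 2 (2.4e-04) and 0.25 without Fli1 KO 2 (9.4e-06). With library size alone it was −0.07 but above other genes in camera (0.0203), since all genes had a median of −0.14 there. Mdm2, the p53 antagonist, rose 1.61-fold (72.6 ± 0.503 to 117 ± 11.1 CPM, log2 fold change 0.68, edgeR adjusted p = 0.0166) and was the only one of 31 p53 and apoptosis genes called by edgeR, against 3 by DESeq2, 2 by limma-voom and 4 by edgeR without NTC 1 or Fli1 KO 2, with 5 higher and 0 lower when p was adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.0794), 0.12 without NTC 1 (0.0317), 0.07 without Fli1 KO 2 (0.0461), 0.12 without Fli1 KO 3 (0.0502), 0.03 without Fli1 KO 1 (0.377) and −0.0041 without NTC 2 (0.411). Mdm2 was not called without Fli1 KO 1 (0.61, 0.218), Fli1 KO 3 (0.72, 0.194) or NTC 2 (0.68, 0.0626).

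Other signalling lists held few calls. Skil, a repressor of TGF-beta signalling, rose 1.83-fold (82.4 ± 1.71 CPM in NTC, n = 2, to 150 ± 21.7 CPM in Fli1 KO, n = 3; log2 fold change 0.87, edgeR adjusted p = 0.00344) and was the only one of 22 TGF-beta genes called, with 3 higher and 1 lower when p was adjusted over the list alone (median 0.07, camera adjusted p = 0.167; fry's mixed test, adjusted p = 0.0274). Without NTC 1, 2 TGF-beta genes were called higher and 2 lower, 5 migration genes higher and 5 lower, 2 interferon genes lower and 1 ETS gene higher. Skil was not called without Fli1 KO 1 (0.78, 0.0905) or Fli1 KO 3 (0.86, 0.0881). Of 27 migration and adhesion genes 2 were called higher (Klf2 and Itgam, the latter 0.46 with adjusted p = 0.468 without NTC 2) and 0 lower, and 2 and 4 with p adjusted over the list alone. Their median of 0.02 and mean of −0.01 differed in sign (camera upward, adjusted p = 0.837). Ifit1bl1, an interferon-induced gene, had the smallest p of 35 type I interferon genes (−0.72, adjusted p = 0.192). edgeR called 0 of these (3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and 0 with p adjusted over the list alone (median −0.07, camera adjusted p = 0.634). Ets2 had the smallest p of 20 ETS factor genes other than Fli1 (11.8 ± 0.728 and 17.6 ± 2.66 CPM, 1.70 times background, 0.58, adjusted p = 0.299). edgeR called 0 of these (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and 0 with p adjusted over the list alone (median 0.03, camera adjusted p = 0.321).

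Most markers of other cells were low in both groups, and with all libraries edgeR called 0 of them (0 also by DESeq2 and by limma-voom). Without NTC 1 it called 4 erythroid and platelet, 3 T cell, 1 B cell and 1 innate lymphoid marker lower and 1 innate lymphoid marker higher. With library size alone or the GC or length correction 1 T cell and 1 B cell marker were called lower. So was the only B cell marker over 3 times background (−0.61), and with no filter 1 T cell and 1 erythroid marker. The corrections, upper-quartile factors, no filter and the fit without Fli1 KO 2 each called 1 innate lymphoid marker higher. The T cell receptor constant gene Tcrg-C1 stood at 5.11 ± 2.82 CPM in NTC (n = 2) and 1.63 ± 0.499 CPM in Fli1 KO (n = 3; log2 fold change −1.61, adjusted p = 0.0903), and the immunoglobulin gene Ighm at 78.5 ± 10.6 and 55.9 ± 7.58 CPM (−0.49, adjusted p = 0.192). The platelet receptor gene Gp1ba (−1.15, adjusted p = 0.166), the macrophage gene Adgre1 (−0.60, 0.449), the basophil protease gene Mcpt8 (0.82, 0.50) and the fibroblast gene Pdgfra (−0.43, 0.480) were under 3 times background. So was Tcrg-C1, at 2.04 times background with 1.45 CPM expected from its length. Klrg1, which mature NK cells also express, had the smallest p of the genes of other innate lymphoid cells (33.4 ± 8.48 and 55.3 ± 11.2 CPM, 0.72, adjusted p = 0.0861). With p adjusted over the list alone, 0 genes were higher and 1 was lower for T cells (17 tested, 5 at an unadjusted p under 0.05) and for B cells (13 tested, 1 unadjusted), 0 and 0 for myeloid cells (19 tested, 3 unadjusted), granulocytes (10 tested, 2 unadjusted) and stroma (13 tested, 1 unadjusted), 0 and 1 for erythroid cells and platelets (9 tested, 3 unadjusted) and 1 and 0 for other innate lymphoid cells (11 tested, 2 unadjusted). The medians were −0.07 for T cells (camera adjusted p = 0.541), 0.02 for B cells (0.634, with a mean of −0.07 and a downward test), −0.08 for myeloid cells (0.136), −0.20 for granulocytes (0.517), 0.02 for stroma (0.956, with a mean of −0.01 and a downward test) and −0.19 for other innate lymphoid cells (0.631). For erythroid and platelet genes, 0 of which exceeded 3 times background, the median was −0.47 (0.0101, with adjusted p = 0.738 with an estimated correlation), −0.34 without Fli1 KO 2 (0.0513) and −0.29 without NTC 2 (0.136).

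The libraries carried reads from outside NK cell genes. Gm10800 (GRCm38 chromosome 2, 98666547 to 98667301) and 8 more predicted genes in satellite repeats took 18.6% (Wilson 95% interval 18.5 to 18.6), 19.8% (19.8 to 19.8) and 16.7% (16.6 to 16.7) of the counts in Fli1 KO 1 to 3, 12.4% (12.4 to 12.4) in NTC 1 and 22.9% (22.8 to 22.9) in NTC 2. Olfactory and vomeronasal receptor genes, which serve sensory neurons, carried 7.54, 9.47, 7.31, 7.98 and 8.51 counts per kb of exon in the same order (1455 autosomal genes). Such a density would make up 21.9%, 27.2%, 22.1%, 21.8% and 30.4% of the remaining counts. Xist, the RNA of the inactive X chromosome, had 7115, 7110, 7142, 6440 and 4051 counts, and 8 Y-linked genes had 1, 0, 8, 0 and 1. By chi-square per degree of freedom over all tested genes, satellite genes included, NTC 1 and NTC 2 differed most (10.1, and 2.09 to 3.35 between Fli1 KO libraries). Their satellite shares of 12.4% and 22.9% were also the furthest apart, so this measure does not describe NK cell transcripts alone. By Pearson correlation Fli1 KO 1 and NTC 2 differed most (0.938, and 0.965 between NTC 1 and NTC 2).

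**Figure D3:**
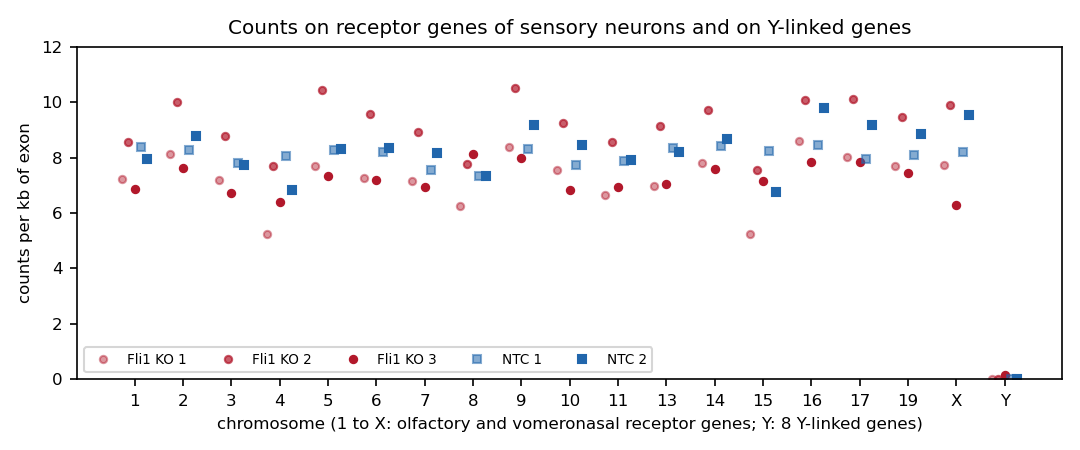
Counts per kb of exon on olfactory and vomeronasal receptor genes by chromosome, and on 8 Y-linked genes, with one point per library (circles, Fli1 KO; squares, NTC). The autosomal density was 7.54, 9.47, 7.31, 7.98 and 8.51 counts per kb for Fli1 KO 1 to 3, NTC 1 and NTC 2, and the Y-linked genes had at most 8 counts in a library.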

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

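All 167 called genes kept their direction under each alternative that tested them. Their groups did not overlap with all libraries, so a change of sign was unlikely and this is no separate support. Of the 46 named genes with a call, 41 to 46 kept it under the planned scalings, filters, DESeq2 and limma-voom. Leaving out 1 library kept 22 (Fli1 KO 1), 43 (Fli1 KO 2), 27 (Fli1 KO 3), 45 (NTC 1) and 37 (NTC 2). Of the 15 lists called by camera, 10, 14, 14, 15 and 4 kept their call in the same order. The immediate early list (0.82 to 0.97 with 1 library left out) and the ER stress list (0.19 to 0.46) kept theirs with every left-out library. So did the glycolysis and hypoxia list and the cytokine and STAT5 list. All of these lists also kept their call under every scaling and filter. The simulation, with these depths, this spread and 3 against 2 libraries, recovered 20% of changes of 1.5-fold over 3 times background and 0% below it, where it also recovered only 38% of changes of 2-fold. The comparison rests on 2 NTC libraries that differ, and the cause of the changes below was not tested unless given. Without NTC 1 or NTC 2 that difference is not part of the spread, so more calls in such a fit are no support.

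Leaving out 1 library in turn gave 46 to 703 higher and 3 to 174 lower genes. The medians ran from 0.0348 to 0.3003 for chaperones, 0.0562 to 0.2574 for the proteasome, 0.0478 to 0.1762 for autophagy, −0.1227 to 0.7783 for cholesterol and fatty acid synthesis and −0.2916 to 0.5941 for the cell cycle. Of these, the lowest values of the chaperone, lipid and cell cycle lists came without NTC 2.

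With an estimated correlation the lists for chaperones (0.1292), ER stress (0.3533), the proteasome (0.1289), autophagy (0.113) and immediate early genes (0.8601) were not called (adjusted p = 0.738 for each), nor with fry (adjusted p = 0.568, 0.464, 0.595, 0.530 and 0.102). Both settings keep the medians and change only the test. Camera was not run with DESeq2 or limma-voom.

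Library size alone gave 92 higher and 71 lower genes and medians of −0.0038 for the proteasome (adjusted p = 0.00126), −0.0162 for autophagy (0.0825) and −0.066 for the cell cycle (0.0203). All 3 lay above the median of all genes, −0.14, because this scaling lowers every value by about the same shift. No filter gave 239 and 56 genes, with more genes tested. The stricter filter left autophagy at 0.089 (0.0800). Upper-quartile factors (0.05, 0.0462) and no filter (0.09, 0.0478) brought the cell cycle list past the threshold. Itgam (0.61, 0.10), Mdm2 (0.55, 0.0554) and Myc (0.59, 0.0607) were not called with library size alone, Itgam not with limma-voom (0.77, 0.0508), H2-K2 not with DESeq2 (−0.89, 0.0535) and Adgrg5 not over 3 times background (−1.05, 0.0536).

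The replicate block, with the replicate number in the model, gave 728 higher and 193 lower genes, among them all 167, and changed no list's call. The numbers are not said to pair the libraries, and only 2 are shared, so Fli1 KO 3 forms a block of its own. It adds nothing to this comparison, which rests on 2 assumed pairs and has little left to estimate the spread from. The larger count of calls and the kept calls are therefore no support. Deviations from the group means correlated at 0.38 for number 1 and 0.56 for number 2, but also at 0.33 between Fli1 KO 3 and NTC 1, which share no number, and with 2 NTC libraries their deviations mirror each other, so these values are no sign of pairing.

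Of the alternatives added after seeing the data, genes over 3 times background gave 139 higher and 59 lower genes and medians of −0.0077 for chaperones, 0.007 for the proteasome and 0.0066 for autophagy, because scaling on these genes removes their common shift of 0.11. The GC correction gave 182 and 95 genes and medians of −0.0176 for autophagy (adjusted p = 0.0327), −0.0443 for the cell cycle (0.0113) and −0.0492 for p53 targets (0.0479), each above other genes in camera. The length correction gave 211 and 118 genes and medians of −0.0035 for autophagy (0.0394) and −0.0312 for the cell cycle (0.0142), likewise above other genes. Of the lists called, that of erythroid and platelet genes had too few tested genes for a value over 3 times background and with the stricter filter.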

Other observations

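Inside the Fli1 gene itself, counts on an annotated transcript of unknown coding status were higher in the libraries labelled Fli1 KO. Gm38346 (GRCm38 chromosome 9, 32507745 to 32510383, 2639 bp) lies in an intron of Fli1, on its strand and with 0 bp of overlap with its exons. It was 2.11-fold higher (9.87 ± 0.225 CPM in NTC, n = 2, to 20.8 ± 1.95 CPM in Fli1 KO, n = 3, log2 fold change 1.08, SE 0.19, edgeR adjusted p = 0.00551). Fli1 had a log2 fold change of 0.25. The counts on Gm38346 were a mean of 3.99 times background, with 4.14 CPM expected from its length. Unspliced Fli1 RNA and a separate transcript cannot be told apart in these counts. Gm38346 had a log2 fold change of 1.03 to 1.15 when any 1 library was left out. It is one of 16 genes of the GENCODE class TEC, transcripts awaiting an experimental test, that were called higher, against 0 called lower, of 2495 tested. All 16 lie inside another gene, as do 1687 of the 2495 tested. They are annotated on its strand, and 13 do not overlap its exons. Strand and exon overlap were not counted for TEC genes that were not called. The strand setting of the counter is not given, so the strand of the reads is unknown. Satb1, a chromatin organizer gene, holds 3 of them (C230085N15Rik, Gm37248 and Gm36931, log2 fold changes 0.80, 0.93 and 1.09, Satb1 itself 0.31).

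Some called genes outside the fixed lists and the naming rule were chosen after their values were seen. The kinase gene Pim3 rose by 1.92 on the log2 scale, the translation factor gene Eif1 by 1.47, the growth arrest gene Gadd45g by 1.52 and the nuclear long noncoding RNA Malat1 by 0.80 (2688 ± 25.7 CPM in NTC, n = 2, to 4691 ± 676 CPM in Fli1 KO, n = 3, edgeR adjusted p = 0.0276). Pramef8, a member of a germline gene family, rose by 1.18 (23.9 to 54.0 CPM), and reads shared with its paralogues leave that value uncertain.

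The tests of explanations below for the immediate early genes and for the background were chosen after the result was seen, as were those of the host genes and of a general rise for the TEC genes, while those of genomic DNA and GC content for the TEC genes were written before.

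Immediate early and AP-1 genes lay higher in Fli1 KO, with a median 0.88 above that of all genes. A GC trend between libraries is argued against, since a per-library correction left the median 0.90 above all genes, and so is a length trend, with 0.89. In 17 of the 17 called members the groups did not overlap, as in all other called genes, which an effect of the knockout and a difference in stimulation or handling before lysis both predict. These cannot be told apart, because the labels give no day or batch and each group may have been handled together. An effect of the knockout on this signalling stays a hypothesis.

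Counts on genes that NK cells do not use are consistent with genomic DNA of the cells. Receptor genes on the X chromosome carried 1.02 times (SD 0.0947, n = 5 libraries) the counts per kb of those on autosomes. This is what 2 copies of each predict. Only 9 receptor genes (35.5 kb) lie on the X chromosome, and the SD between libraries does not measure the spread between genes. Reads assigned at random are argued against, since 8 Y-linked genes reached at most 2.09% of the autosomal density in libraries that carry Xist. How much of the count of a single low gene comes from this source stays open. No biological explanation was tested.

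TEC genes inside other genes lay higher in Fli1 KO, with a median log2 fold change of 0.58 and 49 of 59 positive among those over 3 times background. More genomic DNA in these libraries cannot be judged from the 1628 intragenic TEC genes under 3 times background, which had a median of −0.0267. Only 7678 of 29752 tested genes with a known length exceeded that level, so the scaling itself removes a common shift of genes near background. Before scaling, background at an even density per kb would make up 21.9%, 27.2% and 22.1% of counts outside satellite genes in Fli1 KO. In NTC it would make up 21.8% and 30.4%. These shares overlapped between the groups. A GC trend is argued against, with a median 0.52 above all genes after correction and 0.59 before. A general rise of intronic RNA and higher transcription of the host genes cannot be told apart from a change in the TEC transcripts. The 46 not called had an intermediate median of 0.40 (36 positive). Those called had 1.08, a gap that is partly built in because the call selects large values. The host genes had a median of 0.28 over 17 pairs of TEC gene and host, in which Satb1 counts 3 times and A330023F24Rik more than once. Unspliced RNA of the host genes may account for part of the pattern, and the number of TEC genes called was 5 without Fli1 KO 1, 8 without Fli1 KO 3 and 14 or 15 without any other library.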
